A study of Arabidopsis thaliana with 6 samples.

How the data were processed

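The series holds polyA RNA-seq of roots of Arabidopsis thaliana, accession Col-0. There were 3 libraries of wild type and 3 of a line that expresses NPC48 from 35S, the strong and broadly active promoter of cauliflower mosaic virus. Groups and replicate numbers were taken from the labels. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels, all plants grew on medium with 500 µM phosphate, at 33% humidity, 24 °C by day and 21 °C by night, with 16 h of light. Their growth stage is given as Boyes 1.0.

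The authors deposited raw read counts per gene, one file per library, with no normalization. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts and Subread 1.6.5 were used with the genome build TAIR10. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping or antisense genes cannot therefore be told apart, and the values of genes with near-identical copies, such as jacalin-related lectins, are uncertain. The files hold 29613 gene IDs, of which 28494 matched the reference annotation of assembly TAIR10.1. Because that build differs in version from TAIR10, it was used for names, chromosome numbers, gene order and distances between neighbours, and no coordinates are given.

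Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 19608, and libraries were scaled by TMM. DESeq2 was run on the counts without this filter, so its calls come from a larger set of genes. The comparison used edgeR's quasi-likelihood F test with genotype as the single term, and Benjamini-Hochberg adjusted p under 0.05. Expression is given as CPM, computed from the deposited counts with TMM-scaled library sizes. Fold changes are log2 of 35S:NPC48 over wild type, with the standard error taken from the F statistic.

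The labels give both genotypes the replicate numbers 1, 2 and 3, with the same letters in their titles, and it was checked whether equal numbers deviate together. The correlations across genes of the deviations from the group means were 0.53, 0.83 and 0.37 for replicates 1, 2 and 3, each above 0.1, so the numbers were read as pairing the libraries. For wild type replicate 1 the correlation with 35S:NPC48 replicate 3 was 0.39, and for wild type replicate 3 that with 35S:NPC48 replicate 1 was 0.34. Replicates 1 and 3 were thus hardly told apart. Deviations from a group mean cancel out, so a replicate 2 that stands apart makes replicates 1 and 3 correlate in any combination. The check therefore speaks for the pairing of replicate 2 only. The pairing comes from the numbers in the labels and this check, not from a stated shared day. The fit with the replicate number as a block is given beside a result where it changed the call or moved a count by more than 1.5 times. Counts of the libraries of each within-group pair differed by far more than sampling noise, with chi-square per degree of freedom from 16.3 to 96.1, so no library was counted as a copy.

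Before the data were examined, 22 pathway lists and 6 lists of cell type markers were fixed with 545 members, all of them in the files. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. Called members were counted over all genes tested and adjusted over the list alone. The genes named were also set by rule beforehand. They are NPC48 and its neighbours if matched, then the 10 raised and 10 lowered genes with the largest fold among called genes with a mean of at least 1 CPM and no overlap between groups. Up to 4 called members of each list that passed, single called members of other lists, and the 4 most abundant shoot genes complete the rule. For AT3G01260, ABCB3 and the other genes, the rule was applied to the calls without a block and, after seeing the data, to the blocked calls and to those outside the chromosome 3 run. Members of passing lists that were not called, genes of the chromosome 3 run other than those of the rule, and phosphate genes were named after their values were seen.

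Clustering of called genes was tested by counting adjacent tested genes called in the same direction against 10000 permutations of gene positions, one-sided. A run of raised genes on chromosome 3 was then noticed, and the run of neighbouring genes with the highest summed score was located. A score was the mean of the 3 within-replicate log2 differences minus 0.5, after limiting the score to between -1 and 1. It was set against 1000 shuffles of the gene order, and each replicate was left out in turn and measured in the run found from the others. The interval of the run's median is a 95% bootstrap over its genes with 10000 draws, and genes are not independent replicates. For a gene with 0 counts in a group, the fold was bounded with a floor of 3 counts over the group, which covers counting error only.

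The fits were tested on simulated counts of 19423 genes with 200 changed genes of more than 1 log2 CPM in each of 5 simulations, drawn from the means, library sizes and replicate effects of these libraries. For 35S:NPC48 against wild type, the fit without a block found 5.6% of 2-fold and 72.8% of 4-fold changes with 0 false calls. The fit with the block found 90.0% and 99.6%, and 10.5% of its calls were false. Alternatives covered the scaling, the filter, the test, the threshold, the block and each library left out. DESeq2 and limma-voom with the block, the omission of replicate 2, the omission of the run and a correction for GC content and length were added after seeing the data.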

Results

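Roots of wild type Col-0 and of the 35S:NPC48 line were compared by polyA RNA-seq with 3 libraries each, to ask which genes change when NPC48, known as a non-protein-coding RNA, is overexpressed. Total counts were 21232247, 21055370 and 23830604 in wild type replicates 1, 2 and 3 and 9479418, 20789863 and 20120659 in those of 35S:NPC48, and 19608 genes were tested. The name NPC48 matched 0 of the 29613 gene IDs and 0 entries of the reference annotation. Its level was not analysed here, so the overexpression itself was not checked, and no other gene was put in its place.

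The roots of the 35S:NPC48 line had lost nearly all transcripts of AT3G01260, annotated as a galactose mutarotase-like protein, and of ABCB3 (AT4G01820), an ABC transporter of the P-glycoprotein type. AT3G01260 stood at 137 ± 68.2 CPM in wild type and 0.587 ± 0.355 CPM in 35S:NPC48 (SD, n = 3 each), a log2 fold change of -8.01 ± 0.61 (SE). ABCB3 stood at 11.6 ± 3.23 CPM and 0.871 ± 0.0807 CPM, with a log2 fold change of -3.74 ± 0.30. A run of 166 neighbouring tested genes on chromosome 3, seen in the data and then tested on the same data, had a median 1.97-fold higher in 35S:NPC48. With the replicate number as a block, the lectin genes JAL22 and JAL33 were also raised, and remained called when the run was left out of the adjustment.

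In edgeR's quasi-likelihood test without a block, AT3G01260 and ABCB3 were the 2 genes called, both with an adjusted p of 0.0259, and 0 genes were raised. There were 695 genes at an unadjusted p under 0.05. DESeq2, run without the filter on low counts and with 23816 genes tested, called 105 raised and 48 lowered genes. On the filtered genes, limma-voom called 0 (698 at an unadjusted p under 0.05). Leaving out any library except wild type replicate 2 left edgeR with 0 calls. With the replicate block, edgeR called 165 raised and 72 lowered genes, AT3G01260 with an adjusted p of 5.06e-07 and ABCB3 with 0.00221. The block pairs replicates 1 and 3 across genotypes by their numbers alone, and no fit with that pairing exchanged was run. In the blocked model 0 of 19608 genes were called different between replicates 3 and 1. In simulated counts 10.5% of the blocked calls were false. The blocked total of 237 became 118 when both libraries of replicate 2 were left out and 1938 when both of replicate 3 were. Leaving out a replicate also leaves fewer libraries for estimating the spread. These totals therefore cannot be read as the influence of a replicate alone. Groups did not overlap in 7.76% of tested genes, where chance gives 10% if the libraries are exchangeable. Replicate 2 of both genotypes stood apart, so the libraries were not exchangeable and the 10% is no fair baseline here.

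**Figure D1:**
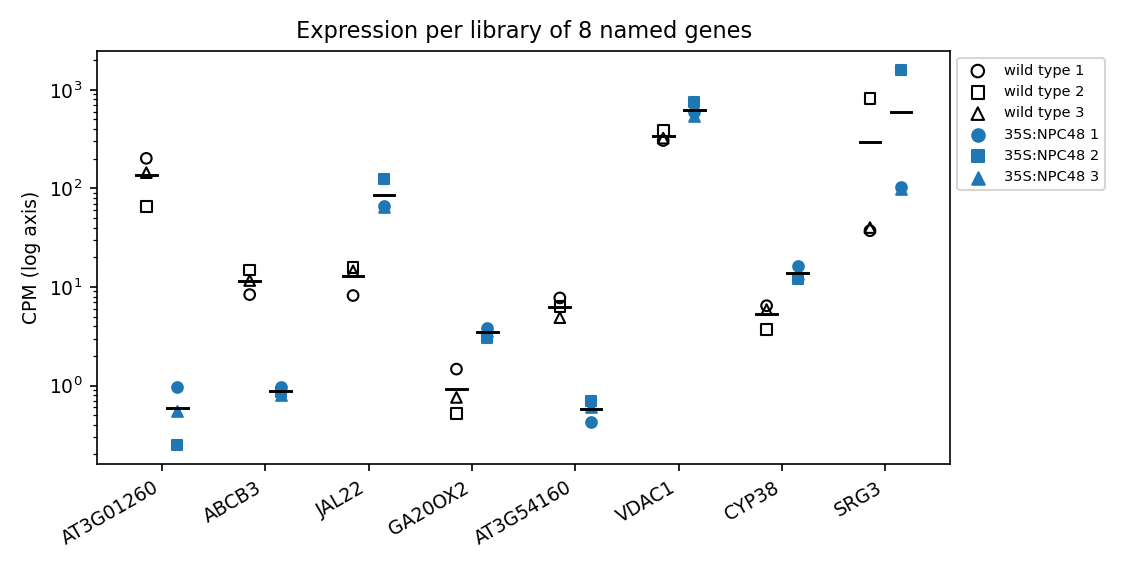
CPM on a log axis of 8 named genes in the 6 libraries. Open symbols are wild type, filled symbols 35S:NPC48, the symbol shape gives the replicate and short bars are group means; AT3G01260 and ABCB3 lie below 1 CPM in all 3 libraries of 35S:NPC48, and SRG3 (GDPD1) is highest in replicate 2 of both genotypes.

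The raised genes were concentrated in one stretch of chromosome 3 that runs from VDAC1 (AT3G01280), a voltage-dependent anion channel of the outer mitochondrial membrane, to AT3G03010. Its 166 tested genes had a median log2 fold change of 0.98 with the replicate block (95% bootstrap interval over genes 0.94 to 1.02), which is 1.97-fold, and 160 of them were higher in 35S:NPC48 in all 3 replicates. VDAC1 rose from 339 ± 43.2 to 630 ± 109 CPM and the membrane protein gene HIR2 from 740 ± 152 to 1380 ± 441 CPM (SD, n = 3 each), both called with the block (edgeR adjusted p = 0.00582 and 0.0235). The heat shock factor gene HSFA1E had a log2 fold change of 0.98 ± 0.13 with the block. The potassium channel gene SKOR, which loads the xylem, had a log2 fold change of 1.08 ± 0.16 with the block. Of the 10 most raised genes among those called with the block that had a mean of at least 1 CPM and no overlap between groups, 6 lie in this stretch, namely GASA5, LYK2, TRXF1, AT3G02245, CYP38 and AT3G01850, with log2 fold changes between 1.35 and 1.92 in the blocked fit. Some genes of the stretch that did not meet all of these conditions had higher values, such as AT3G02500 with 2.52 and COL2 with 2.14 in the blocked fit. AK3 (AT3G02020) had a log2 fold change of -0.06 ± 0.32 with the block and 0.23 ± 0.59 without it. Its replicates differed, with 37.2, 78.3 and 68.5 CPM in wild type replicates 1, 2 and 3 and 37.5, 146 and 31.3 CPM in those of 35S:NPC48. AT3G01890 had 0.36 ± 0.13 with the block.

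The lowered gene AT3G01260 is the tested gene next to VDAC1 on the outer side, and HB20 beyond it had a log2 fold change of 0.01 ± 0.11 with the block. Over the 20 tested genes before the stretch the median was -0.04, and over the 20 after it 0.02. AT3G03020, the first tested gene after it, had a log2 fold change of 0.52 ± 0.31 with the block and was not called. The medians of the stretch were 1.01, 1.00 and 0.93 in replicates 1, 2 and 3. When the stretch was located from the other replicates alone, the held-out replicate gave 1.01, 0.99 and 0.93. With replicate 1 or 2 held out the stretch included AT3G03020 and had 167 genes, and with replicate 3 held out it ended at AT3G03010. Its summed score was 76.4, against a highest value of 2.85 in 1000 shuffles, and the best raised run on any other chromosome held at most 2 genes. The annotation places 237 genes in the stretch, of which 214 have counts listed and 48 of those were too low to test. The share of all counts in these 214 genes was 0.963% in wild type and 1.79% in 35S:NPC48.

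**Figure D2:**
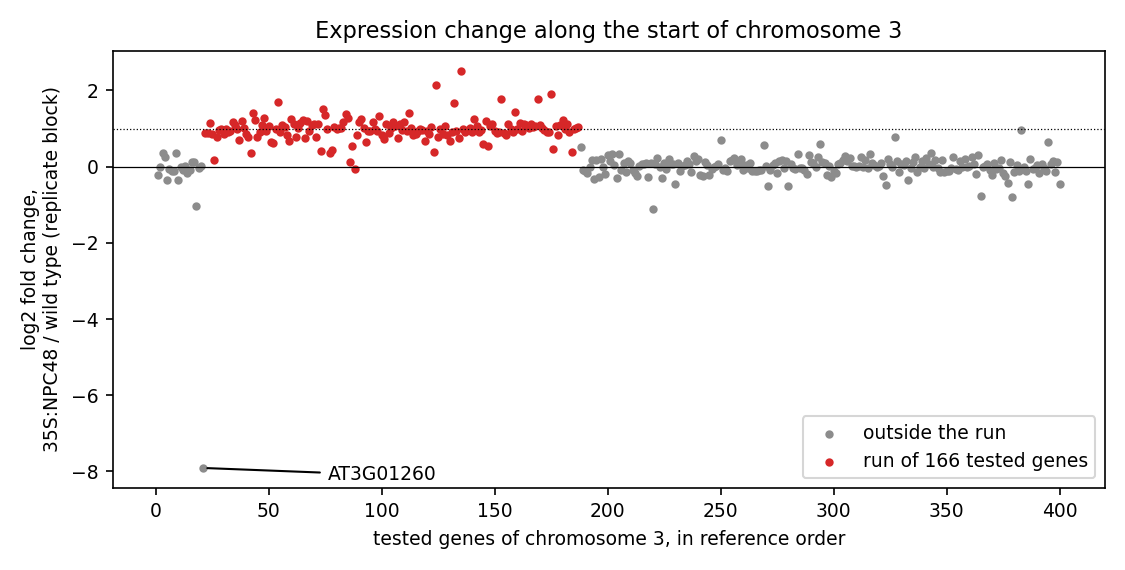
Log2 fold change of 35S:NPC48 over wild type (replicate block) for the first 400 tested genes of chromosome 3 in reference order. The 166 genes of the run, positions 22 to 187, are in red and lie around 1 (dotted line), and the gene before them, AT3G01260, lies near -8.

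Among tested genes, 89 adjacent pairs were called in the same direction with the replicate block, where permutation gave 1.63 on average and 9 at most (permutation p = 1e-04, the smallest that 10000 permutations can give). With the run left out, 1 such pair remained (permutation p = 0.28). Without the block there were 0 pairs among the 2 called genes. Of the blocked calls, 122 raised genes lay in the run and 43 outside, while all 72 lowered genes lay outside. In the edgeR fit without a block, 0 of the run's genes passed, although the median log2 fold change there was 0.98 as well. DESeq2 without a block called 105 raised genes, of which 97 lay in the run.

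Outside the run and with the replicate block, JAL22, a jacalin-related lectin, rose from 12.8 ± 4.06 to 85.0 ± 33.5 CPM (log2 fold change 2.71 ± 0.18, edgeR adjusted p = 0.00221). Its relative JAL33 rose from 210 ± 81.1 to 451 ± 241 CPM (1.04 ± 0.12, adjusted p = 0.00556). With the run in the adjustment, GA20OX2, a gibberellin 20-oxidase, rose from 0.916 ± 0.493 to 3.48 ± 0.425 CPM. AT4G33720, of the CAP superfamily, rose from 0.994 ± 0.438 to 4.46 ± 1.78 CPM. The genes AT5G66815, AT1G73120, AT2G26370, scpl5, AT2G17710 and AT3G20160 rose with log2 fold changes from 0.91 to 1.59. When the run was left out of the adjustment, 4 raised genes were called with the block, namely JAL22 (edgeR adjusted p = 0.00277), JAL33 (0.0285), AT2G17710 (0.0285) and the glycine-rich protein gene GRP3S, which was named after its values were seen. The calls of the other 7 genes were then lost, with adjusted p from 0.0527 for AT5G66815 to 0.0826 for AT4G33720, and 0.0685 for GA20OX2. Without the block none of these 10 genes was called, JAL22 having an adjusted p of 0.0741.

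Several lowered genes outside the run were close to undetected in 35S:NPC48. ALMT12, a malate-activated anion channel known from guard cells, had 0 counts in all 3 libraries of 35S:NPC48 against 2.75 ± 1.81 CPM in wild type, at least 45.3-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.00732 with the block). Without wild type replicate 2 this bound was 28.2-fold. AT3G54160, annotated as an RNI-like protein, fell from 6.33 ± 1.43 to 0.576 ± 0.140 CPM (log2 fold change -3.33 ± 0.28 with the block, adjusted p = 0.00287). AT3G28770, AT5G39330, AT5G27037, AT5G44980 and AT4G04223 fell with blocked log2 fold changes from -3.65 to -2.73. CYP71B12, a cytochrome P450, fell from 4.82 ± 2.52 to 0.927 ± 0.427 CPM. Of these genes, 0 passed without the block, AT3G54160 being closest with an adjusted p of 0.0563. When the run was left out of the adjustment, 32 lowered genes were called with the block, and AT3G28770 (edgeR adjusted p = 0.0749) and AT5G44980 (0.0716) were not among them.

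Of the 28 gene lists, 4 passed camera with the preset correlation, and edgeR called 0 of their members without the block. The iron acquisition list was higher in 35S:NPC48 (adjusted p = 0.0191), with 18 of 30 tested members positive and a median log2 fold change of 0.30. With an estimated correlation its adjusted p was 0.946, and with fry 0.977. Its iron transporter gene IRT1 had 43.5 ± 7.39 CPM in wild type and 84.3 ± 29.0 CPM in 35S:NPC48, and the ferric reductase gene FRO2 33.1 ± 6.14 and 57.5 ± 30.3 CPM, while the nicotianamine synthase gene NAS4 had 3.33 ± 1.31 and 1.78 ± 0.281 CPM. Adjusted over the list alone, 0 members passed without the block and 5 with it. The iron list did not pass without wild type replicate 2 (adjusted p = 0.287), without both replicate 2 libraries (0.317), or with the block without replicate 2 (0.308). The nitrate list was lower (adjusted p = 0.0362), with 24 of 28 members negative and a median of -0.14. With an estimated correlation its adjusted p was 0.946, and with fry 0.977. The nitrate reductase gene NIA2 had 459 ± 107 and 335 ± 66.3 CPM. Adjusted over the list alone, 0 members passed with or without the block. The nitrate list did not pass without wild type replicate 1 (0.122) or 3 (0.882) or 35S:NPC48 replicate 2 (0.542) or 3 (0.0704), with no filter on low counts (0.0607), or with the block without replicate 3 (0.764).

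Of the cell type markers, the suberin list was higher in 35S:NPC48 (adjusted p = 0.0336, and 0.946 with an estimated correlation), with 11 of 14 members positive and a median log2 fold change of 0.17. KCS2, a fatty acid elongase of suberin synthesis, had 66.5 ± 18.9 CPM in wild type and 107 ± 11.2 CPM in 35S:NPC48 and was called with the block (0.71 ± 0.12, edgeR adjusted p = 0.0337, and 0.0749 with the run left out of the adjustment). The shoot and chloroplast list was higher as well (adjusted p = 0.0191, and 0.946 with an estimated correlation), with 21 of 23 members positive and a median of 0.27. PSBR, a photosystem II subunit, had 32.2 ± 11.7 and 42.5 ± 4.71 CPM, and the antenna gene LHCB4.1 had 17.9 ± 5.56 and 21.5 ± 9.25 CPM. The median of the shoot list was 3.12 log2 CPM in wild type replicate 3 and 2.90 in 35S:NPC48 replicate 1, and between 0.86 and 1.49 in the other libraries. The suberin list did not pass without wild type replicate 1 (adjusted p = 0.656) or 35S:NPC48 replicate 2 (0.257) or 3 (0.0689), nor the shoot list without wild type replicate 1 (0.622) or 2 (0.971) or 35S:NPC48 replicate 1 (0.934). The shoot list did not pass without both replicate 2 libraries (0.260) either. With the block, the shoot list did not pass without replicate 1 (0.965) or 2 (0.303), nor the suberin list without replicate 1 (0.433). Adjusted over the list alone, 1 suberin gene and 0 shoot genes passed with the block, and 0 of either without. The endodermis, xylem, phloem and root cap lists did not pass (adjusted p from 0.533 to 0.769). CASP5, a Casparian strip protein of the endodermis list, was called with the block, at 10.9 ± 5.04 and 23.2 ± 12.6 CPM (1.08 ± 0.17, edgeR adjusted p = 0.0263, and 0.0685 with the run left out of the adjustment).

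With the block, the root hair list (camera adjusted p = 0.0287) and the flavonoid list (0.00762) were lower in 35S:NPC48 too. With the block and an estimated correlation, the adjusted p was 0.917 for both. In the fit without a block, 17 of 20 root hair members and 6 of 8 flavonoid members were negative. Neither list passed camera there (adjusted p = 0.442 and 0.214). Adjusted over the list alone, 0 root hair genes and 4 flavonoid genes passed with the block. In blocked fits the root hair list did not pass without replicate 2 (adjusted p = 0.233) or 3 (0.617), nor the flavonoid list without replicate 3 (0.168). The flavonol synthase gene FLS1 had 59.3 ± 49.2 CPM in wild type and 40.0 ± 43.5 CPM in 35S:NPC48, with 115 and 90.0 CPM in replicate 2. Both lists were themselves higher in replicate 2 than in replicate 1, by a median log2 of 1.28 for root hair genes and 2.17 for flavonoid genes. Other lists had single members called with the block: ACO1, an ACC oxidase of ethylene synthesis (0.77 ± 0.13, adjusted p = 0.0326, and 0.0734 with the run left out of the adjustment), and, within the chromosome 3 run, LBD41 of the hypoxia list (0.91 ± 0.16) and GDPD1, named SRG3 in the reference, of the phosphate starvation list (1.24 ± 0.12). ACO1 and LBD41 also passed without the block when adjusted over the list alone. The phosphate starvation list as a whole did not pass, with 11 of 26 members positive, a median of -0.06 and an adjusted p of 0.851, although the direction of the test was up. The lists for low-phosphate signalling, sulfate, cell cycle, meristem regulators, auxin, cytokinin, ethylene, jasmonate, immunity, abscisic acid, heat shock, hypoxia, oxidative stress, the clock, glucosinolates, small RNAs and flowering did not pass either, with adjusted p from 0.125 for hypoxia to 0.917. Adjusted over the list alone with the block, 1 raised and 3 lowered of 13 tested flowering genes passed, and 2 lowered of 16 abscisic acid genes. The medians of the hypoxia, ethylene and phloem lists were below 0 while their means and tests pointed up. For low-phosphate signalling the mean was above 0 while the median and test pointed down, and for flowering the mean was below 0 while the median and test pointed up. The number of passing lists became 7 without wild type replicate 3 and 8 without 35S:NPC48 replicate 2.

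Replicate 2 of both genotypes stood apart from replicates 1 and 3. SPX1, a phosphate sensor gene induced by phosphate shortage, had 7.97, 1266 and 6.78 CPM in wild type replicates 1, 2 and 3 and 7.67, 1004 and 12.5 CPM in those of 35S:NPC48. The noncoding RNA IPS1 had 0.267, 393 and 0.505 CPM in wild type and 0.320, 313 and 0.650 CPM in 35S:NPC48. In the blocked model, 24 of 26 phosphate starvation genes were called higher in replicate 2 than in replicate 1, with a median log2 difference of 4.21 over the list. Over all genes, 2108 were higher and 1803 lower in replicate 2 than in replicate 1, and 2215 were higher and 2032 lower than in replicate 3. Between replicates 3 and 1 the median of the phosphate starvation list differed by a log2 of 0.16. The labels give 500 µM phosphate for all 6 libraries. The first principal component held 57.6% of the variance and separated replicate 2, and the second held 15.8% and separated the genotypes. Without both replicate 2 libraries, edgeR called 28 raised and 18 lowered genes with no block, 27 of the raised ones in the run, and 87 raised and 31 lowered with it.

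**Figure D3:**
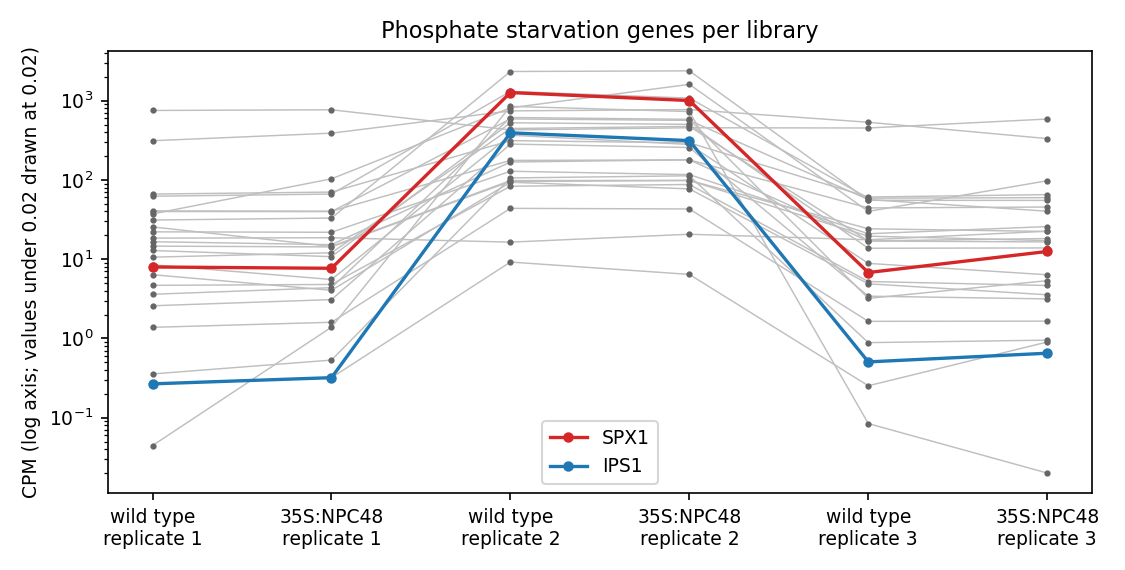
CPM on a log axis of the 26 tested phosphate starvation genes in the 6 libraries, with values under 0.02 drawn at 0.02. Each line joins the values of one gene, with SPX1 and IPS1 in colour, and 24 of the genes were called higher in replicate 2 than in replicate 1.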

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

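The following alternatives were chosen after seeing the data: DESeq2 and limma-voom with the replicate block, both replicate 2 libraries left out, the block without each replicate, with the run left out, with the GC and length correction, with an estimated correlation or with fry, and the adjacent pairs under the block. NPC48 had no match, so NPC48 expression gave no value under any alternative. The count of 2 changed genes in 35S:NPC48 against wild type was 237 with the replicate block, 153 with DESeq2, 0 with limma-voom, 0 at an adjusted p under 0.01, 336 with DESeq2 and the block, 237 with limma-voom and the block, 46 with both replicate 2 libraries left out, 36 with the block and the run left out, and 309 with the block and the GC and length correction. Leaving out single libraries gave 0 to 2, and the block gave 191, 118 and 1938 without replicates 1, 2 and 3, and the cause was not tested. Blocked fits without a replicate have very few libraries left for estimating the spread. AT3G01260 and ABCB3 each passed in 16 of 22 alternatives (adjusted p up to 0.329), with log2 fold changes from -8.40 to -7.61 and from -3.99 to -3.53. The count of 4 lists passing the set test was 0 with an estimated correlation, with fry, and with either under the block, and ranged from 3 to 8 without single libraries. The iron list passed in 14 of 21 alternatives (adjusted p from 0.00151), suberin in 13 (from 8.27e-04), shoot in 11 (from 2.23e-13) and nitrate in 11 (from 2.10e-06), each with a highest adjusted p of 0.977. Adjacent pairs, 0 without the block, were 89 with the replicate block, 282 with it within 10 kb, and 88 with it and tandem copies left out. The median of the chromosome 3 run stayed between 0.93 and 1.00 in all 21 alternatives. Beyond the calls given with the block in the report, the block changed no list's call.

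Some directions turned, and the cause was not tested. The shoot list turned under the block without replicate 1 (adjusted p = 0.965). Over the libraries left out, the root hair list went from an adjusted p of 2.41e-05 (without wild type replicate 1) to 0.906 and turned without wild type replicate 2 (0.287) and 35S:NPC48 replicate 1 (0.906), and the flavonoid list went from 0.001002 to 0.971, turning without wild type replicate 2 (0.971). Log2 fold changes went from -0.15 to 0.46 for LHCB4.1, turning without 35S:NPC48 replicate 1, and from -1.58 to 3.96 for SRG3 (GDPD1), turning without 35S:NPC48 replicate 2. Turning without wild type replicate 2, they went from -0.44 to 0.047 for RHD2, -1.18 to 0.51 for UGT78D1, -1.98 to 0.37 for FLS1 and -2.25 to 0.77 for TT7. With all 6 libraries, none of these genes was called by edgeR without the block, and SRG3 was called with it. In simulated counts with these library sizes and replicate effects, the fit without the block found 5.6% of 2-fold changes and the blocked fit 90.0%. Those counts were drawn from the blocked model, which favours the blocked fit.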

Other observations

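Replicate 2 differed from the other replicates in more than phosphate genes, and in both genotypes. Root hair genes were higher, with 17 of 20 called against replicate 1, and 16 of 30 cell cycle genes were called higher, while 14 of 28 nitrate genes were called lower. The potassium channel gene SKOR had 157, 10.9 and 82.7 CPM in wild type replicates 1, 2 and 3 and 239, 26.2 and 218 CPM in those of 35S:NPC48. The iron superoxide dismutase gene FSD1 had 351, 16.0 and 388 CPM in wild type and 508, 19.6 and 445 CPM in 35S:NPC48. FRO4, named for the ferric reduction oxidase family, had 57.6, 2.75 and 70.8 CPM in wild type and 52.6, 3.26 and 65.8 CPM in 35S:NPC48. These genes were named after their values were seen.

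Of the tests below, the GC and length corrections, the linkage of lowered genes and the other splits were set before their results were seen, and the gene order, copy and phosphate tests after.

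The run of raised genes on chromosome 3 had an SD of log2 fold change of 0.32 over its genes, against 0.27 in genes outside it matched on expression. A GC content or gene length trend is argued against, because the median log2 fold change was 0.98 before and 0.98 after correction in the blocked fit. Activation spreading from one end of the run is argued against too, as Spearman's rho between fold change and gene order across its genes was 0.0855 (permutation p = 0.275, two-sided). A candidate explanation is an additional copy of the segment in the 35S:NPC48 line. Of the run's tested genes, 84.3% lay between 1.5- and 2.5-fold. This is a hypothesis found and tested on the same data. The range was set after the values were seen and holds the median of 1.97-fold, so it cannot tell the number of copies. Fewer copies in the wild type libraries, or an even activation of the whole stretch, would give the same ratio and stay open, as DNA was not analysed here.

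The replicate 2 libraries of both genotypes held very high phosphate starvation transcripts. A GC content or gene length trend is argued against, since the list's median, replicate 2 minus 1, was 4.23 after correction. A lower phosphate supply to the plants of replicate 2 may account for it, but the list's median of 4.21, against 0.42 at most in 10000 random lists matched on expression, is the observation itself and tests nothing further. The labels give the same phosphate level and the same growth stage (Boyes 1.0) for all plants, so this and other differences in growth or age stay open.

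The genes lowered in 35S:NPC48 outside the run were spread over all 5 chromosomes. Of the 69 lowered genes placed on a chromosome, 5.80% had another within 10 tested genes, where permutation gave 6.76% on average (one-sided permutation p = 0.69). This argues against dense clusters of lowered genes in linked regions carried along with the transgene. A linked region with few or scattered lowered genes would not be seen by this count. AT3G01260 lies next to the run, whose genes were left out of the count. Whether NPC48, the insertion or older differences between the lines lowered them was not tested.

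With 10 splits of the 6 libraries into groups of 3, no share under 0.05 can be reached. The real split gave 2 changed genes and the highest of the others 0, with 1 of 10 splits reaching the real value. With the block there are 4 ways to exchange genotypes within replicates, and the real one gave 237 genes against 0 in each of the others, again 1 that reached the real value. For gene lists, 8 of 10 splits gave at least the real 4, the highest being 12 in splits that put both replicate 2 libraries on one side. With the block, 2 of 4 gave at least the real 6, the highest other being 6.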
